A study of Homo sapiens with 8 samples.

How the data were processed

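Total RNA from frozen human colon biopsies, 4 of normal colon and 4 of colon cancer, was amplified and labelled with Cy3 by random priming along the whole transcript, per the labels' protocols, and hybridised to 1 single-colour Agilent array per sample. The deposited scanner output of each array was used as the main source. Per the file headers and the submitters' processing notes, it was made with Agilent Feature Extraction 11.0.1.1, on a design annotated to GRCh37. The deposited processed signal is an intensity per spot on a linear scale, background-subtracted and spatially detrended by the scanner software, per the file headers, and not normalized between arrays. The deposited flags, a further kind of column that holds 0 or 1 per spot, mark spots well above background, saturated spots and outlier spots, per the file headers.

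The log2 of the processed signal was taken, and the 75th percentile of each array over its non-control probes was subtracted. Control spots and spots with an outlier flag were left out, saturated spots were kept (there were 0), and the 10 spots of each named probe were averaged. A probe was tested if it was well above background on at least 4 of the 8 arrays, which 39935 probes were. A further 53 had too few unflagged values, which left 39882. Differences between cancer and normal samples were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, and p was adjusted by the Benjamini-Hochberg method over all tested probes with a threshold of 0.05. Nothing in the labels pairs the samples, so no pairing was used. Where a probe was not well above background on any array of 1 group, its difference is given as a lower bound. The bound is the mean of the other group against the mean, over the arrays of the dim group, of the higher of the probe's own signal and the lowest signal among probes well above background on that array. Single values per array were compared by an exact two-sided permutation test of group means, whose smallest p with 4 against 4 is 0.0286.

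On simulated data with the probes' own means and pooled spread, 200 of 39474 probes were changed by a known amount. The noise was Gaussian, independent between probes and of equal spread in the 2 groups. The test recovered 8 of 100 probes changed by 1 log2 unit and 52 of 100 changed by 2, with 3 false calls. With 3158 probes changed by 1.5 log2 units it recovered 73.5%, and 4.95% of the calls were false. Differences near 2-fold could therefore be missed when few probes change. In the real data the cancer samples spread more than the normal samples, so the recovery and the share of false calls may differ there.

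Gene names came only from the accessions of 20 probes, all matched through a RefSeq gene table of the assembly GRCh38.p14, from which no coordinates were taken. The 29 gene lists, the tests of the comparisons, most of the alternative settings and the rule for naming genes were fixed before the data were examined. The settings and tests added later are named as such with their results. The rule takes the 5 named coding and 5 named non-coding genes with the largest difference in each direction among those past the threshold with no overlap between groups, or, if none pass, the 3 with the smallest p, and the members of each fixed list with the smallest p. It leaves out sex-linked marker genes and genes whose level follows a common inherited variant. It allowed a few unnamed probes to be given by identifier, but these exclusions cannot be applied to a probe of unknown gene, so no unnamed probe is given singly. The range over the named genes, with PFN1 and GRM4, was added after their values were seen. No gene list had the 5 measured genes required for a test, and no named probe was non-coding, so the planned tests of lists and counts by coding class were not run.

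The deposited value table of the authors holds log2 values of 21658 probes, all of them among the 39935 probes that passed the filter. The rule that chose these 21658 is not given in the sources used here. The scale was settled by comparison with the scanner values of the same array and probe. Column medians were 6.50, 6.56, 6.47 and 6.51 for normal replicates 4 to 7 and 6.49, 6.49, 6.50 and 6.58 for cancer replicates 11 to 14. Against a quantile normalization of the log2 processed signals computed here, the table's values differed by a median of at most 0.000236 in size and an SD of at most 0.0101 on any array. The direction follows, since each column is 1 array's own level, and no centring of probes was present.

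Per the file headers, the arrays lay on 2 slides of 4 arrays, 1 slide per group, and all carried the same scan date. Because each group filled 1 slide, a fit with the slide as a block could not be made. The alternatives were quantile and median normalization, normexp background correction with an offset of 50, the authors' table, no filter, a filter on all 8 arrays, array weights, an intensity trend with a robust prior, a 2-fold minimum, a two-sample test per probe without a shared variance, and each replicate left out. Normexp had been planned on the mean signal and was run on the median signal, since the scanner columns used here hold no mean signal.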

Results

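RNA levels were compared between 4 samples of normal human colon and 4 samples of human colon cancer, the question being which transcripts, long non-coding RNAs in the first place, differ between cancerous and normal colon tissue. Each sample was hybridised to its own single-colour array, and the labels describe the samples of a group as biological replicates. The array carried 60904 probes known here only by the manufacturer's identifiers and 20 probes with a transcript accession. All 20 accessions were matched to a gene. The identifiers of the other probes are not paired with genes, or with a coding or non-coding class, in the files and tables used here, so these probes are described as groups. Between 38092 and 41858 probes were well above background on an array. In all, 33321 probes were well above background on all 8 arrays, and 13597 were not well above background on any. The number of arrays limits the precision of every value below.

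The normal samples resembled one another more closely than the cancer samples did. The median Pearson correlation across probes was 0.970 for the 6 pairs of normal samples (0.964 to 0.979), 0.942 for the 6 pairs of cancer samples (0.919 to 0.961) and 0.916 for the 16 pairs of a normal with a cancer sample (0.894 to 0.936). Probes are not independent replicates, so these values only describe the arrays. The first principal component held 44.6% of the variance and separated the groups, and the second held 19% and spread the cancer samples apart.

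**Figure D1:**
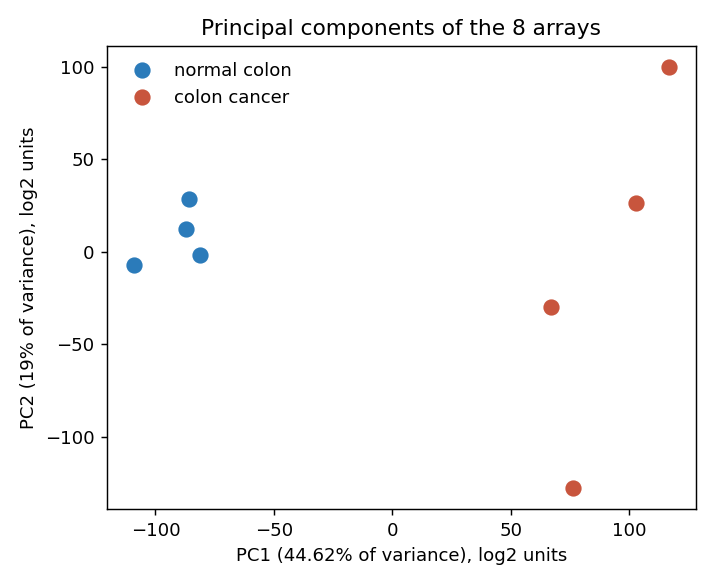
Each point is 1 sample, placed by its scores on the first principal component (horizontal axis, 44.6% of the variance) and the second (vertical axis, 19% of the variance) of the log2 signals, in log2 units. The 4 normal samples lie together on the left, and the 4 cancer samples lie on the right and are spread out along the vertical axis.

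Transcript levels differed widely between cancer and normal colon, and the larger differences were mostly losses. Of 39882 probes tested, 3052 (7.65%) had an adjusted p under 0.05 in limma's moderated test, of which 1305 were higher and 1747 were lower in cancer. The median difference was 2.50-fold among the higher and 3.31-fold among the lower probes, with probes not well above background in 1 group entered at their lower bound. Differences of at least 8-fold were found for 95 higher and 369 lower probes, and of at least 32-fold for 14 higher and 109 lower probes. Among the probes well above background on all 8 arrays, the balance of calls turned, with 1268 higher and 1212 lower. This filter leaves out by construction any probe seen in 1 group only. Over all tested probes, the direction of the calls varied with brightness. At 4 levels of mean signal, from dimmest to brightest, 135, 213, 400 and 557 calls were higher. The lower calls numbered 447, 423, 486 and 391, so lower calls were not in excess at the brightest level. Differences of at least 2-fold were found for 920 higher and 987 lower of the filtered probes. Differences of at least 8-fold were found for 70 higher and 179 lower, counts added after seeing the data. The 4 cancer values lay wholly above or below the 4 normal values for 3011 of the 3052 probes, and for 16.7% of all tested probes, where chance gives 2.86%. All normal samples lay on 1 slide and all cancer samples on another, so slide and group cannot be told apart. The counts were 358 higher and 809 lower with array position as a block, a fit added after seeing the data, 576 and 913 with an adjusted two-sample test per probe, and 217 and 484 in the authors' table, which holds fewer probes. The counts also changed when 1 sample was left out, which leaves fewer arrays for the fit. Without normal replicate 4, 5, 6 or 7, the higher probes numbered 722, 510, 556 and 589 and the lower probes 1091, 1148, 993 and 1090. Without cancer replicate 11, 12, 13 or 14, the higher probes numbered 1219, 958, 639 and 1571 and the lower probes 1716, 1392, 1156 and 1732.

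**Figure D2:**
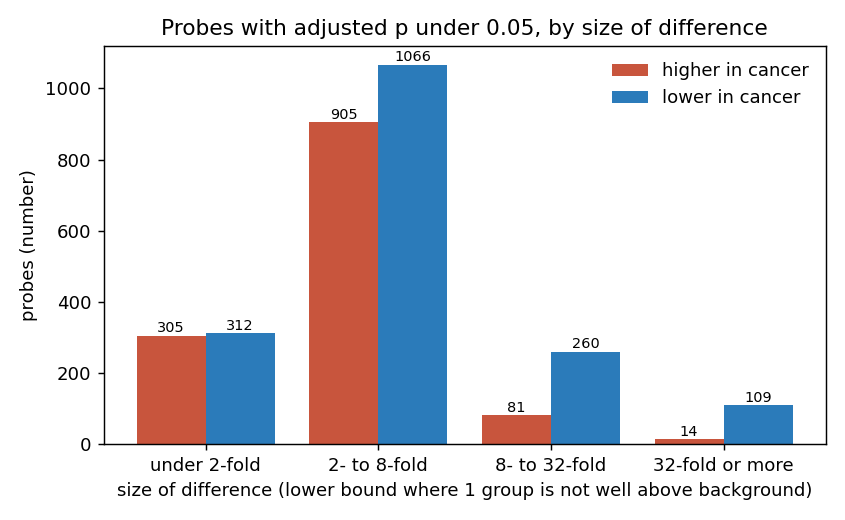
Bars give the number of probes with an adjusted p under 0.05 (vertical axis) by the size of the difference between 4 cancer and 4 normal samples (horizontal axis, in fold classes, with the lower bound used where a probe was not well above background in 1 group), for probes higher and lower in cancer. In the 2 upper classes, 260 and 109 probes were lower in cancer against 81 and 14 that were higher.

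When only detection was considered, loss of signal was more frequent than gain. The lowest signal among probes well above background was also 0.165 log2 units higher on average on the cancer arrays (exact permutation p = 0.0571). A group of 333 probes was well above background in all 4 normal samples and in no cancer sample, and 59 probes were seen in all 4 cancer samples and in no normal sample. In the first group 263 probes passed the threshold of limma's test, and in the second 54 did. The median normal-only probe was at least 2.02-fold lower in cancer, and the median cancer-only probe was at least 3.07-fold higher. A bound of at least 2-fold held for 170 of the normal-only and 44 of the cancer-only probes. With the 95th percentile of the negative control spots as the limit, the groups held 155 and 39 probes. Leaving out a sample can raise these counts but not lower them, since fewer arrays must meet the condition. Without cancer replicate 11 the normal-only probes numbered 526. Without normal replicate 7 the cancer-only probes numbered 105, and without cancer replicates 11, 12 and 14 they numbered 91, 100 and 139. The number of probes well above background per array was 40250 ± 1328 (SD, n = 4) in normal and 38824 ± 524 (SD, n = 4) in cancer samples, which an exact two-sided permutation test did not separate (p = 0.114). With normal replicate 6 left out, the exact permutation test gave p = 0.0286.

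The 20 probes with an accession represent mostly genes that nearly all cells express, and none of the 19 that were tested passed the threshold of limma's test after adjustment over all probes. At an unadjusted p under 0.05 there were 2, ODC1 and GAPDH. The 3 with the smallest p were ODC1, GAPDH and PRMT1. ODC1, ornithine decarboxylase, the first enzyme of polyamine synthesis, differed by 0.77 on the log2 scale between cancer and normal samples (SE 0.31, 1.70-fold, adjusted p = 0.176). GAPDH, a glycolytic enzyme, differed by 0.59 (SE 0.25, adjusted p = 0.1997). PRMT1, a protein arginine methyltransferase, differed by 0.76 (SE 0.34, adjusted p = 0.222). The differences of the 19 genes ran from -0.33 for PFN1, the actin-binding protein profilin, to the value of ODC1. GRM4, a glutamate receptor gene, was not well above background on any array.

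**Figure D3:**
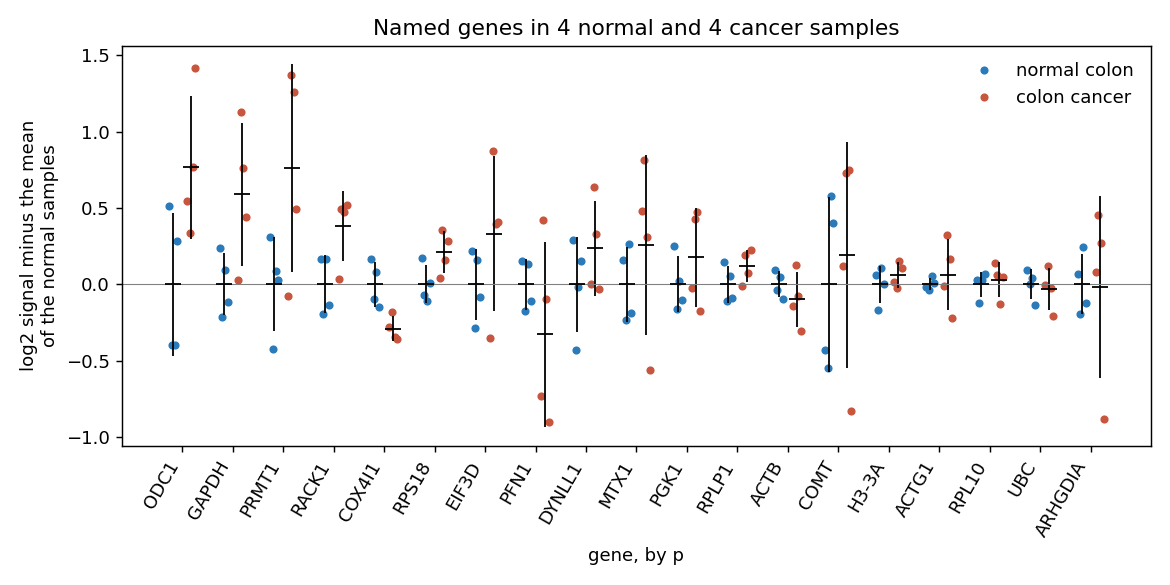
Points give the log2 signal of 19 named genes (horizontal axis, ordered by p) in each of 4 normal and 4 cancer samples, relative to the mean of the normal samples (vertical axis, log2 units), with horizontal marks at the group means and vertical lines of 1 SD either way. ODC1, GAPDH and PRMT1 had the largest positive mean differences (0.77, 0.59 and 0.76), none past the threshold, and for COX4I1 alone the groups did not overlap.

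Among the gene lists fixed beforehand, oxidative phosphorylation and hypoxia had 1 measured gene each. COX4I1, a nuclear-encoded subunit of cytochrome c oxidase, had a log2 signal of 9.77 ± 0.15 (SD, n = 4) in normal and 9.48 ± 0.08 (SD, n = 4) in cancer samples. Its difference was -0.29 (SE 0.15), with an adjusted p of 0.277 over all probes and 0.309 adjusted over the list alone, the list being the 19 named genes. Its groups did not overlap, as was the case for 16.7% of all tested probes. PGK1, a glycolytic enzyme, differed by 0.18 (SE 0.20, adjusted p = 0.661 in limma's test). The manufacturer's control probes for PGK1 gave other values, with differences of 0.61 for the 3' probe (exact permutation p = 0.143) and 0.76 for the 5' probe (exact permutation p = 0.0286, and 0.0971 after adjustment over the array measures). For GAPDH the 3' and 5' control probes differed by 0.61 and 0.88 (exact permutation p = 0.0857 for each). The 5' signal relative to the 3' signal was 0.27 higher in cancer for GAPDH and 0.16 higher for PGK1 on the log2 scale (exact permutation p = 0.0857 for each). Labelling was randomly primed along the whole transcript, so these values are not read as a measure of RNA integrity.

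Levels varied more among the cancer samples than among the normal samples. The median SD per probe was 0.304 in normal and 0.385 in cancer samples on the log2 scale, a ratio of 1.27, and 63.8% of 39474 probes had the larger SD in cancer. The cancer SD exceeded 2 times the normal SD for 10687 probes, and the reverse held for 4115. The root mean square deviation of a sample from its group mean was 0.413 ± 0.047 (SD, n = 4) in normal and 0.604 ± 0.081 (SD, n = 4) in cancer samples, with no overlap. A two-sided permutation of these values gave p = 0.0286, and 0.0971 after adjustment over the 17 array measures compared. The 4 values of a group share 1 mean and are not independent, so this p is not an exact test of the spread. Without cancer replicate 14 the ratio of the median SDs was 1.07, and it averaged 1.15 when a normal sample was left out as well, so that 3 samples were set against 3.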

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

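The test of the slides, and the comparison of the spread with a normal sample left out as well, were chosen only after the results were seen. Leaving out 1 cancer sample was added once the data had been seen, with its limits set before its result.

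Of the 35 splits of the 8 samples into 4 and 4, only the real one gave as many as 3052 probes past the threshold. The highest of the other splits gave 1. A share of 1 in 35 is the smallest these splits can give. The other splits mix cancer with normal samples, so their low counts do not measure how many probes would pass by chance. The differences of neighbouring spots correlated at only 0.0108 across 50206 pairs, which argues against a defect over much of the array surface. A defect of a small patch could leave this single correlation low and is not excluded. A difference between the slides stays open. The bright corner control spots lay at -0.96 on the log2 scale on the cancer slide relative to the normal slide after scaling, with SDs of 0.34 and 0.27 within the slides. Whether their signal depends on the sample is not given in the sources used here. Slide and disease cannot be told apart because each group filled 1 slide. The biological difference between cancer and normal tissue therefore remains a hypothesis beside it.

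The 333 probes seen in all normal samples and no cancer sample were likewise the largest count of the 35 splits, with 86 as the highest of the others. Again 1 of 35 is the smallest share possible, and the other splits mix the groups. Lower sensitivity of the cancer arrays may account for part of these probes. A lower-bound fall of at least 1 log2 unit was present in 51.1% of them (exact binomial 95% interval 45.5% to 56.5%), too close to the 50% set in advance to decide. The interval takes the probes as independent, which they are not, and does not cover the variation between samples. The lowest signal among probes well above background averaged 0.165 log2 units higher on the cancer arrays (exact permutation p = 0.0571). Of 25 control probes for other targets seen on no array, 21 had a higher mean in cancer, with a median difference of 0.141 over the 25. A loss of transcripts in cancer and a slide effect on dim signals both stay open.

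The larger spread among cancer samples, a ratio of the median SDs of 1.27, could not be traced to noise or to 1 sample. The variance between replicate spots on cancer arrays was 2.46% of the extra variance, but spots of 1 array do not measure the noise of labelling and hybridisation, so noisier arrays stay open. A single divergent cancer sample may account for part of it, as the ratio of 1.07 without cancer replicate 14 met the limit of 1.1 set in advance, but that limit did not allow for the number of samples. The median SD of 3 samples lies below that of 4 by construction, and with 1 normal sample left out as well the ratio averaged 1.15 (1.06 to 1.24). The 3 pairs of cancer samples without replicate 14 correlated less (highest 0.961) than any pair of normal samples (lowest 0.964), and variation between tumours was not tested apart from this.

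In 68 groups of 4 values, 3 had a sample far from the others, where chance gives about 3.4. The number of probes above the 95th percentile of the negative control spots had its lowest cancer sample 961 probes below the next, a gap of 0.938 of the range. The number of outlier-flagged spots had its highest normal sample 307 spots above the next, a gap of 0.841 of the range. RACK1, a ribosome-associated scaffold protein, had its lowest cancer sample 0.43 log2 units below the next, a gap of 0.900 of the range.

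Some signals outside the comparisons were higher in all 4 cancer samples than in all 4 normal samples. Negative control spots were 0.25 higher on the log2 scale before scaling (exact permutation p = 0.0286, and 0.0971 adjusted over the array measures). Of 61 control probes for other targets, 21 were well above background on all arrays, and 2 of these were higher without overlap, the rat PGK1 5' probe by 0.75 and the probe ETG05_36762 by 0.16. The lowest adjusted p over the 61 probes was 0.232.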

How the results depend on the processing

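The counts of probes higher and lower in cancer stayed within 1.5 times of 1305 and 1747 with quantile or median normalization, normexp, no filter, a filter on all 8 arrays, array weights, an intensity trend, a 2-fold minimum, and a two-sample test at unadjusted p under 0.05 with 2-fold. With the filter on all 8 arrays, however, they were 1268 and 1212, so the excess of lower probes did not hold there. That filter removes by construction the 263 normal-only and 54 cancer-only probes past the threshold. Of the full fit's calls, 2313 were probes well above background on all 8 arrays, 1162 of them higher and 1151 lower. The excess in number of lower calls therefore lay among probes that were not well above background on at least 1 array. At 2-fold or more, 920 of the filtered probes were higher and 987 lower. They were 217 and 484 in the authors' table, which holds fewer probes, 576 and 913 with the two-sample test after adjustment, and 358 and 809 with array position as a block, which leaves fewer degrees of freedom. The position block, normexp on median signals, fits of the table's probes alone, the negative-control limit for probes seen in 1 group only, and all alternatives for the spread were chosen after seeing the data. With each replicate left out in turn, the higher probes numbered 510 to 1571 and the lower 993 to 1732. Of the 1571 and 1732 without cancer replicate 14, 1007 and 1392 were shared with the full fit. Probes seen only in normal samples numbered 355 to 526 and only in cancer samples 67 to 139, counts that leaving out a sample can raise but not lower. With the limit from negative control spots they were 155 and 39, where the cause was not tested. The difference in probes well above background ranged from -1964 to -889 per array and the ratio of the median SDs from 1.07 to 1.47. None of ODC1, GAPDH, PRMT1, COX4I1 and PGK1 passed the threshold or changed sign under the 17 alternatives run for them, with adjusted p of 0.0704 (PRMT1) or more. Probes not well above background on any array of 1 group carry bounds only. Probes dim on only some arrays of a group carry differences without such a bound. No paired analysis was possible because the replicate numbers of the 2 groups do not overlap. The slide block, the gene lists and the counts by coding class were not run.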

Other observations

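The test of identifier order was chosen only after the result was seen.

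The 21658 probes of the authors' table changed less often than the other probes on the array. Among those tested, 4.92% passed the threshold (333 higher and 732 lower in cancer), against 10.9% of the 18233 probes outside the table (972 higher and 1015 lower; Fisher's exact p = 3.59e-111 across probes, which are not independent). With p adjusted over the table's probes alone, 207 were higher and 513 lower. The table's probes were dimmer, with a median log2 scaled signal of -2.01 against 0.61. The gap was present at each of 4 levels of signal, from 4.76% against 9.83% in the dimmest to 4.99% against 10.9% in the brightest.

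Probes with consecutive identifiers differed alike between cancer and normal samples. The Pearson correlation of their differences across probes was 0.132 for 27662 pairs 1 number apart, 0.06 at 2, 0.04 at 3, 0.02 at 5, 0.0092 at 10 and -0.0058 at 50. The largest correlation in 1000 random orders of the identifiers was 0.0181 (permutation p = 0.001, the smallest they can give). A candidate explanation is that consecutive identifiers hold transcripts of 1 gene or of neighbouring genes. The correlation of 0.132 only restates the pattern and does not test this, which needs the genes of the probes. Past the threshold, the longest run of consecutive identifiers that were all lower in cancer held 6 probes. The longest run that were all higher held 4.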
